A study of Arabidopsis thaliana with 12 samples.

How the data were processed

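Total RNA from whole roots was labelled with biotin by the Affymetrix 3′ IVT procedure, per the labels, and hybridized to 12 arrays, 3 for each combination of genotype (Ws or afb3-1) and treatment (5 mM KCl or 5 mM KNO3 for 2 h). The values used were the deposited log2 signals of 22810 probe sets, which the authors had already processed. The background correction, the normalization and the summarization are not given in the sources used here. The scale was read from the values: the hybridization controls bioB, bioC, bioD and cre rose by 0.909 per doubling of their usual concentration. After each array was sorted, no value lay more than 0.176 from the mean of the sorted arrays, the pattern left by a normalization between arrays, so values were used without a further one. Such a normalization hides a shift shared by most genes. Summarized signals near the floor of the scale understate fold changes. Arrays have no read depth, and their number limits the precision.

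The 64 array control probe sets were left out, which left 22746 for testing. Gene names came from the GEO platform annotation, updated through Entrez gene identifiers to the TAIR10.1 RefSeq gene table. A single gene was given for 13513 probe sets, several for 503 and none for 8730. Of the 13513, 13436 matched the gene table and 77 kept the older name. A probe set without a name here still measures a transcript, and one with several genes was not named. Where a gene had more than 1 probe set (147 of 13355 genes), the one with the highest mean over all arrays stood for it. No coordinates are given, because the build behind the probe annotation is not given in the sources used here.

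Groups were taken from the sample titles. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (8 residual and 3.20 prior degrees of freedom). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets of a contrast, with a threshold of 0.05. The contrasts were nitrate in Ws, nitrate in afb3-1, the difference of these (afb3-1 minus Ws), and afb3-1 minus Ws in KCl and in KNO3. The overlap of nitrate calls and the correlation of the 2 nitrate responses use separate arrays for each genotype. The tests, the alternatives named first, the gene lists and the rule for naming genes were set before the data were examined.

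The rule named, per contrast, the 8 largest rises and 8 largest falls past the threshold among probe sets with 1 gene, or the 5 smallest p where none passed. It also named up to 4 members of each gene list past the threshold, or up to 2 with the smallest p given as values, and 9 genes of the study's subject in every contrast, none of which had a named probe set. Of 284 entries in 23 gene lists, 29 had a named probe set (27 genes, in 11 lists). The 4 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a contrast. With a preset correlation of 0.01 the nitrate signalling and reductant lists passed in both nitrate contrasts, and both held with an estimated correlation. In addition 33 gene families were defined by name patterns, and the 23 with at least 3 members were tested. The patterns were written after the annotation was read and before any gene was tested.

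Replicate numbers are shared by all groups. Deviations from the group means of same-numbered arrays of the 2 genotypes correlated by 0.301 to 0.661 within a treatment (6 pairs, all above 0.1), so numbers paired arrays for the genotype comparisons. This pairing comes from the data, since the labels say only that replicates were independent. Across treatments within a genotype the same correlation ran from −0.281 to 0.542, so numbers did not consistently pair KCl with KNO3 arrays. Some arrays did deviate together across treatments. KCl and KNO3 replicate 2 correlated by 0.527 in afb3-1 and 0.542 in Ws. KCl replicate 3 and KNO3 replicate 1 correlated by 0.474 in afb3-1 and 0.543 in Ws. The nitrate contrasts nevertheless took KCl and KNO3 arrays as independent.

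Alternatives were quantile normalization, median centring, leaving out the dimmest tertile of probe sets (mean log2 up to 2.32), the replicate number as a fixed or random block, a fit of only the groups compared, a mean-variance trend with robust moderation, no moderation, array weights, a fold cut-off of 1.5, an adjusted p of 0.1, and leaving out each array in turn. Added after the data were seen were a block for the number within a treatment, a fit without both KCl arrays numbered 3 and a contrast for nitrate averaged over genotypes, fitted to the means of same-numbered pairs, with a random block within a treatment and with arrays taken as independent. List tests whose call changed with a block or without an array were also run there with an estimated correlation, likewise added. The procedure was tested on simulated data with the mean and spread of the 22746 probe sets, 200 of them changed. The simulated arrays varied independently, so the deviations shared by same-numbered arrays were not simulated. For nitrate in Ws it recovered 100% of 4-fold, 77.6% of 2-fold and 17.9% of 1.5-fold changes, all with the right direction, with 9 false calls. Figures were drawn with matplotlib 3.10.9.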

Results

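Whole roots of Arabidopsis thaliana seedlings were profiled on 12 single-colour Affymetrix expression arrays. The plants were the wild-type accession Ws and afb3-1, a mutant in that background of AFB3, one of the TIR1/AFB F-box proteins that serve as auxin receptors. Seedlings grew for 14 days in hydroponic medium with 0.5 mM ammonium succinate as the nitrogen source and 3 mM sucrose. At the start of the light period on day 15 they received 5 mM KNO3 or, as the control for the potassium salt, 5 mM KCl for 2 h. Each of the 4 combinations of genotype and treatment had 3 arrays, described as independent biological replicates. The number of arrays limits the precision of every value. The deposited log2 signals ran from 0.401 to 12.12, and the median over probe sets lay between 3.78 and 3.92 on each array. Arrays of one group correlated with Pearson r between 0.973 and 0.996 across probe sets, and arrays of different groups between 0.960 and 0.995, so no pair looked like one hybridization deposited more than once. AFB3, TIR1, AFB1, AFB2, NAC4, OBP4, NIA1, NIR1 and NRT2.1 had no named probe set and were not analysed here, so the mutated gene could not be used to check the genotype labels.

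The first comparison asked which root genes respond to nitrate in wild-type plants. Nitrate raised 3 GARP-type transcription factors of the HHO group, which act in nitrogen and phosphate signalling, and 2 of the 3 measured 6-phosphogluconate dehydrogenases, PGD1 and PGD3, enzymes that supply NADPH through the oxidative pentose phosphate pathway. HHO1 (AT3G25790) rose from 1.60 ± 0.21 in KCl to 5.84 ± 0.66 in KNO3 on the log2 scale (mean ± SD, n = 3), a 19.0-fold change (adjusted p = 2.3e-05). HHO3 (AT1G25550) rose 9.52-fold (adjusted p = 4.56e-05) and HHO2 (AT1G68670) 8.31-fold (adjusted p = 0.00201). PGD3 (AT5G41670) rose 7.48-fold from 7.90 ± 0.11 to 10.80 ± 0.11 (adjusted p = 4.21e-07, n = 3), and PGD1 (AT1G64190) 3.91-fold (adjusted p = 1.44e-06). The named gene with the largest rise was AT5G10210, with a log2 change of 5.57 ± 0.26 (SE), a 47.5-fold change (adjusted p = 5.57e-07).

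In total 658 of 22746 probe sets changed in Ws at an adjusted p of 0.05, 420 higher and 238 lower with nitrate, against 3016 at an unadjusted p under 0.05. Of these, 281 rose and 71 fell by at least 2-fold. Over all probe sets, the 3 KNO3 arrays lay entirely above or below the 3 KCl arrays for 17.3%, where chance gives 10%. A single named gene was known for 335 of the 658, which came to 333 genes. Besides AT5G10210 and HHO1, the 8 largest named rises were AT2G48080 (log2 change 4.97), PGM (AT1G78050, a phosphoglycerate mutase, 4.16), AT3G07350 (3.73), AT5G62720 (an HPP family membrane protein, 3.68), AT4G18340 (a glycosyl hydrolase of family 17, 3.51) and AT5G59080 (an 11.3-fold rise), with adjusted p between 4.33e-07 and 0.00042. The largest named fall was SUFE2 (AT1G67810), an activator of cysteine desulfurase, which fell by 2.76 ± 0.39 (SE) on the log2 scale (adjusted p = 0.00231). It was followed by AT2G32560, an F-box protein (−2.73), AT4G17670 (−2.53), AT1G64590 (−2.43), AT4G33040, a glutaredoxin (−2.18), EXPA8 (AT2G40610), a cell wall loosening expansin (−1.91), AT5G45650, a subtilisin-like protease (−1.74), and AT1G71970 (−1.68), with adjusted p between 1.43e-05 and 0.00682. A second, dimmer probe set for AT2G32560 did not pass the threshold (−0.32, adjusted p = 0.33).

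By gene list, 3 of the 4 measured nitrate signalling regulators rose in Ws and NRG2 did not pass the threshold (0.30 ± 0.15 SE). The list had a median log2 change of 3.15, and its test against other genes gave an adjusted p of 1.06e-10 (0.00374 as adjusted p with an estimated correlation). Of the 4 measured genes of reductant and carbon skeleton supply, PGD1 and PGD3 rose, while PGD2 (AT3G02360; −0.20 ± 0.11 SE) and cICDH (AT1G65930; −0.28 ± 0.16 SE) did not pass (list adjusted p = 0.000256, or adjusted p = 0.00924 with an estimated correlation). Adjusted over the list alone, the counts were the same 3 and 2. None of the 8 measured auxin-inducible genes passed over all probe sets or adjusted over the list alone. The closest were WES1 (AT4G27260, also called GH3.5, −0.59, adjusted p = 0.189) and LBD29 (−0.51, adjusted p = 0.278), and the list's adjusted p was 0.237, which became 0.0317, with a lower level in nitrate, without Ws KNO3 replicate 2 (adjusted p = 0.195 with an estimated correlation). None of the 3 lateral root initiation genes passed (LBD29 as above and LBD16 at −0.33, list adjusted p = 0.237). Of lists with 1 or 2 measured members, none passed: RR16 (0.11) and ARR15 (−0.03) of cytokinin response, GI (−0.11) of the circadian clock, BHLH101 (−0.21) of iron deficiency, STZ (0.03) of wounding, EXPA7 (−0.27) and EXPA18 (0.00) of root hairs, and LHCB4.1 (−0.52) and RCA (−0.29) of photosynthesis. RR16, ARR15 and BHLH101 were dim, with means of 1.23, 1.89 and 1.59 in Ws KCl. Like IAA29, IAA20 and PUCHI, named below, they lay in the dimmest tertile of probe sets, where fold changes can be understated. The only measured member of the nitrate transport and assimilation list, NRT2.5, a high-affinity nitrate transporter, had a log2 change of 0.18 ± 1.41 (SE), and its signal differed between arrays of one group. It was 4.85, 3.46 and 7.78 in the 3 Ws KCl arrays and 6.77, 3.56 and 6.31 in the 3 Ws KNO3 arrays, in order of replicate number. All 24 probe sets of the spike-in controls dap, lys, phe and thr were lower with nitrate in Ws by point estimate, with a median of −0.40, and the difference of their means was −0.38, or −0.15 without Ws KCl replicate 3. The count of 658 fell to 370 without Ws KNO3 replicate 3, to 338 when only the 6 Ws arrays were fitted and to 400 without variance moderation, and rose to 1220 with array weights.

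The second comparison put the same question to afb3-1. HHO1 rose from 1.42 ± 0.20 to 5.88 ± 0.52 (mean ± SD, n = 3), a 22.1-fold change (adjusted p = 1.43e-05). HHO3 and HHO2 rose 8.67-fold and 8.66-fold (adjusted p = 6.37e-05 and 0.00159). PGD3 rose 7.92-fold and PGD1 3.99-fold (adjusted p = 1.85e-07 and 1.13e-06). AT5G10210 again had the largest named rise, 5.73 ± 0.26 (SE) on the log2 scale or 53.1-fold (adjusted p = 4.09e-07). In total 628 probe sets changed, 408 higher and 220 lower, against 2528 at an unadjusted p under 0.05, and 302 of the 628 had a single named gene. Over all probe sets, the KNO3 arrays lay entirely above or below the KCl arrays for 17.0%, where chance gives 10%.

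The other large named rises in afb3-1 were AT2G48080 (5.12), AT3G07350 (4.29), PGM (a 16.0-fold rise), AT4G18340 (3.86), AT5G19970 (3.58) and WNK7 (AT1G49160, a protein kinase of the WNK family, 3.58), with adjusted p between 1.85e-07 and 3.79e-05. The named falls were led by AT1G64590 (−2.97), AT2G32560 (−2.77), SUFE2 (−2.71), AT4G17670 (−2.16), AT3G21670 (NPF6.4, a member of the NRT1/PTR transporter family, −2.03), AT4G33040 (−1.96), AT1G55760 (a BTB/POZ domain protein, −1.89) and AT5G55050 (a GDSL lipase, −1.71), with adjusted p between 1.05e-05 and 0.0272. The calls of AT3G21670 and AT5G55050 were lost without any of several single afb3-1 arrays. The adjusted p of AT3G21670 was 0.0659 without KCl replicate 1, 0.0925 without KCl replicate 2, 0.101 without KCl replicate 3, 0.0866 without KNO3 replicate 2 and 0.0602 without KNO3 replicate 3. The adjusted p of AT5G55050 was 0.115 without KCl replicate 1, 0.107 without KCl replicate 2, 0.0883 without KNO3 replicate 1 and 0.115 without KNO3 replicate 3. Without variance moderation 5 of these falls did not pass, with adjusted p of 0.0538 for AT4G17670, 0.0659 for AT4G33040, 0.0561 for AT1G55760, 0.115 for AT3G21670 and 0.101 for AT5G55050.

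By gene list, 3 of 4 nitrate signalling regulators rose in afb3-1 (list adjusted p = 4.25e-09, or adjusted p = 0.00646 with an estimated correlation), with NRG2 at 0.06. The reductant and carbon skeleton list again had PGD1 and PGD3 past the threshold (list adjusted p = 0.000519, or adjusted p = 0.0119 with an estimated correlation). Adjusted over the list alone, PGD2 also passed, in the other direction, lower with nitrate at −0.26 ± 0.11 (SE, unadjusted p = 0.034, adjusted p over all probe sets = 0.367), and cICDH (−0.22 ± 0.16 SE) did not. None of the 8 auxin-inducible genes passed (WES1 −0.57, IAA29 0.39, list adjusted p = 0.286). None of the 3 lateral root initiation genes did (LBD29 −0.33, PUCHI 0.10, list adjusted p = 0.686), and that list had a median of 0.04 but a mean of −0.06 and a test direction below 0. No member of the other measured lists passed: ARR15 (0.18), RR16 (0.08), GI (−0.07), BHLH101 (−0.01), STZ (0.44), EXPA18 (−0.39), EXPA7 (−0.19), RCA (0.26), LHCB4.1 (0.20) and NRT2.5 (0.03 ± 1.41 SE). The count of 628 fell to 387, 396 and 380 without afb3-1 KCl replicate 1, KCl replicate 2 and KNO3 replicate 3, fell to 416 without variance moderation, and rose to 1612 with array weights.

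**Figure D1:**
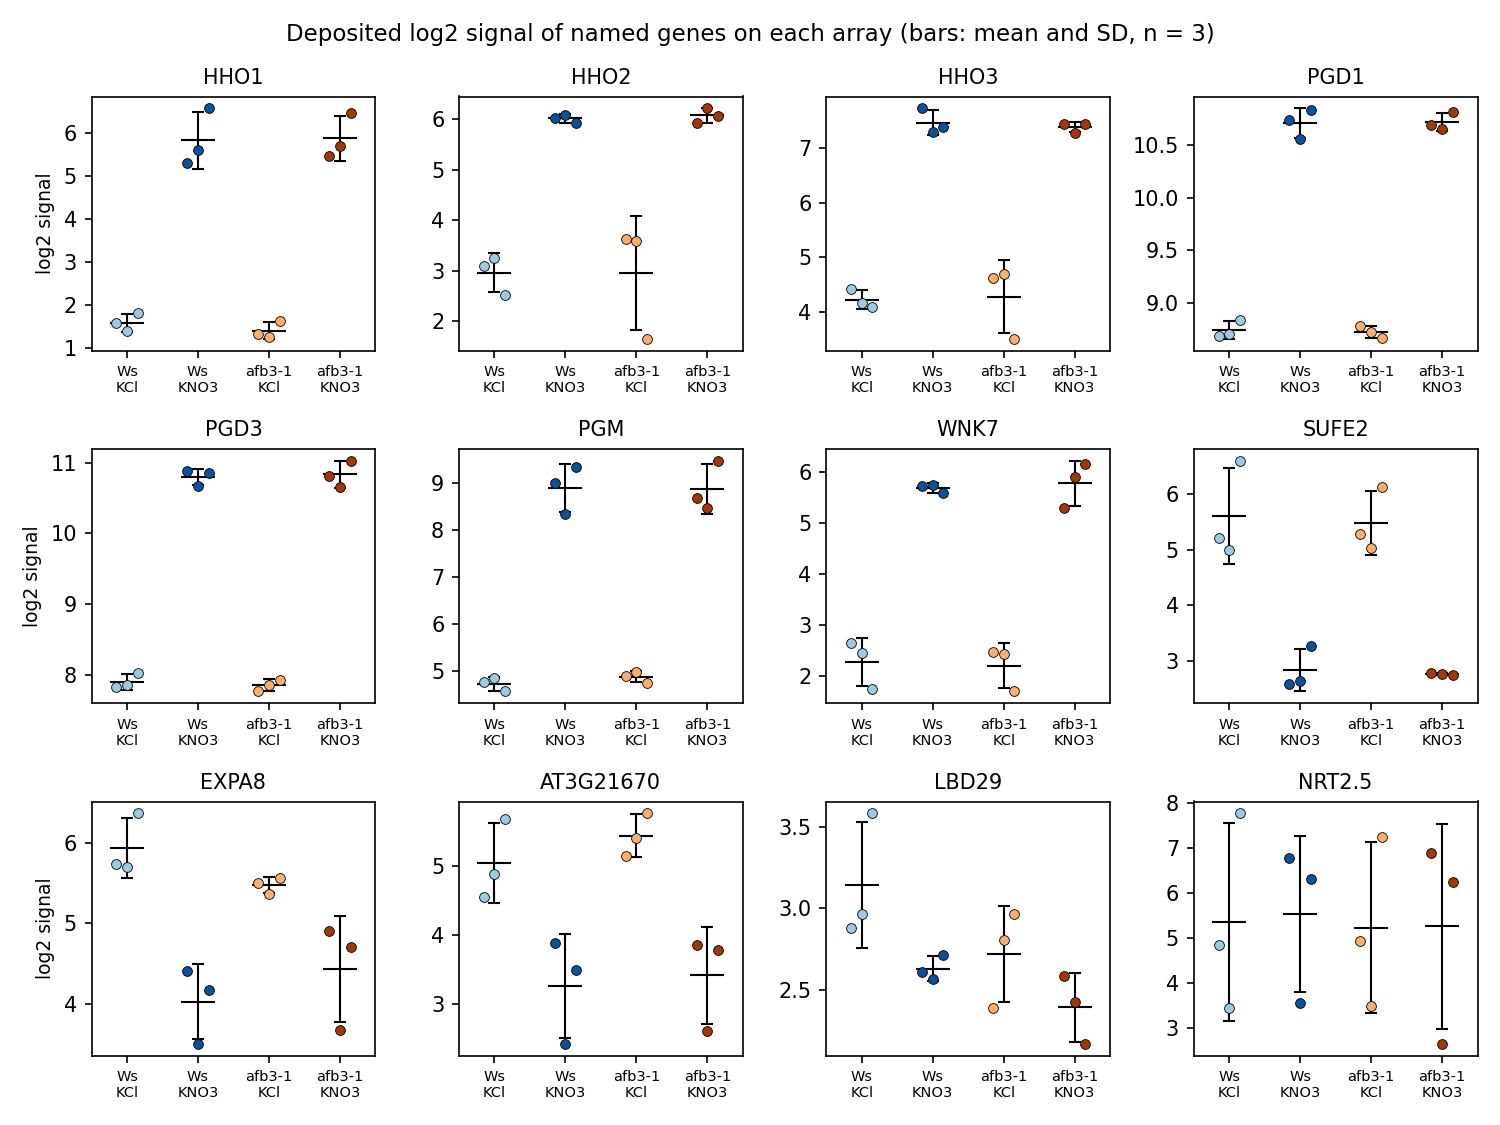
Deposited log2 signal (vertical axis) of 12 named genes on each array, by genotype and treatment (horizontal axis), with points for arrays in order of replicate number and bars for the mean and SD of 3 arrays. HHO1, HHO2, HHO3, PGD1, PGD3, PGM and WNK7 were higher and SUFE2 lower on every KNO3 array than on every KCl array of the same genotype, while NRT2.5 ranged from 3.46 to 7.78 within Ws KCl alone.

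The central question of the design was whether the nitrate response depends on AFB3. No probe set had a nitrate response that differed between genotypes in the limma interaction test (0 of 22746, smallest adjusted p = 0.999), with 664 at an unadjusted p under 0.05, or 2.92% where chance gives 5%. The count was also 0 with an unmoderated linear model. With same-numbered arrays of a treatment as pairs, limma again called 0, with a smallest adjusted p of 0.473. In that fit 9.11% had an unadjusted p under 0.05. The estimates and intervals that follow come from the fit without pairs. That fit keeps the deviations shared by same-numbered arrays in the spread, so intervals for differences between genotypes may be too wide. The same holds for the standard errors given below for afb3-1 against Ws in KCl and in KNO3. For HHO1 the difference of the responses, afb3-1 minus Ws, was 0.22 (95% confidence interval −0.76 to 1.21), for PGD3 0.08 (−0.28 to 0.45) and for PGD1 0.03 (−0.29 to 0.34). EXPA8 fell by 1.91 in Ws and by 1.05 in afb3-1, where it did not pass (adjusted p = 0.15), and the difference was 0.86 (−0.13 to 1.86). The 5 named genes with the smallest interaction p, none past the threshold, were AT2G07719 (0.84 ± 0.18 SE), AT4G29370 (0.80), AT1G71740 (0.89), orfX (1.05) and AT5G19730 (0.59), with unadjusted p between 0.000522 and 0.000909 and an adjusted p of 0.999.

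Calls overlapped between the genotypes. 323 probe sets rose and 131 fell in both, against 7.53 and 2.30 for independent lists, and none changed in opposite directions. The lists would overlap more than independent ones even without a common response. Both contrasts share the estimate of the spread of each probe set, and same-numbered arrays deviated together within a treatment. Of the 204 called in Ws alone, 198 had the same sign in afb3-1 and 158 had an unadjusted p under 0.05 there. Of the 174 called in afb3-1 alone, 170 had the same sign in Ws and 142 had an unadjusted p under 0.05. Among the 832 called in either genotype, 65 had an interaction p under 0.05 (7.81%) and 0 passed when adjusted over the 832 (smallest adjusted p = 0.191). Over all probe sets the share was 2.92%. The 832 were chosen by the same changes whose difference is tested, which can raise the share of small interaction p. Neither the share nor the adjustment over the 832 is therefore an unbiased test of a difference. In the fit without pairs, the 95% interval of the difference had a median half-width of 0.53 on the log2 scale over the 832. In simulated data whose arrays varied independently, without the deviations shared by same-numbered arrays, an interaction of 4-fold was recovered for 92.4% of changed probe sets, of 2-fold for 49.3% and of 1.5-fold for 0%.

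Across all probe sets, which are not independent replicates, the log2 changes in Ws and afb3-1 correlated with Pearson r = 0.755 and Spearman rho = 0.395. Over the 658 called in Ws the Pearson r was 0.979, 652 had the same sign, and the median ratio of the afb3-1 to the Ws change was 0.94. Over the 628 called in afb3-1 that ratio was 1.08. Each list was chosen by the change in its own genotype, which makes the change in the other genotype look smaller. The ratios therefore do not show which genotype responded more, and choosing large changes can also raise the Pearson r. Same-numbered arrays of the 2 genotypes deviated together within a treatment, which adds to the correlations. The covariance of the responses was 0.101 with all arrays. Between single arrays it averaged 0.156 with matching numbers and 0.0738 with other numbers, with Pearson r of 0.663 and 0.349. By gene list, the responses of nitrate signalling regulators (NRG2 −0.24 and HHO1 0.22, adjusted p = 0.852), reductant and carbon skeleton genes (PGD3 0.08 and PGD2 −0.06, adjusted p = 0.956), auxin-inducible genes (IAA29 0.33 and IAA20 −0.25, adjusted p = 0.956) and lateral root initiation genes (LBD16 0.37 and LBD29 0.19, adjusted p = 0.852) did not pass a test of the difference. The test direction of the reductant list was below 0 although its median (0.04) and mean (0.03) were above 0, and the median of the nitrate signalling list was −0.04 as deposited and 0.01 after quantile normalization. Without afb3-1 KCl replicate 3, in which HHO2 and HHO3 were lower than on the other 5 KCl arrays, the nitrate signalling list reached an adjusted p of 0.0384 with a lower response in afb3-1, but adjusted p = 0.234 with an estimated correlation. The 24 spike-in probe sets were all above 0 for the interaction, with a median of 0.43, and the value for their mean was 0.42, or 0.19 without Ws KCl replicate 3. Values for the remaining lists, none past the threshold, were 0.21 for ARR15, −0.03 for RR16, 0.04 for GI, 0.20 for BHLH101, 0.41 for STZ, −0.38 for EXPA18, 0.07 for EXPA7, 0.55 for RCA, 0.72 for LHCB4.1 and −0.15 for NRT2.5.

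**Figure D2:**
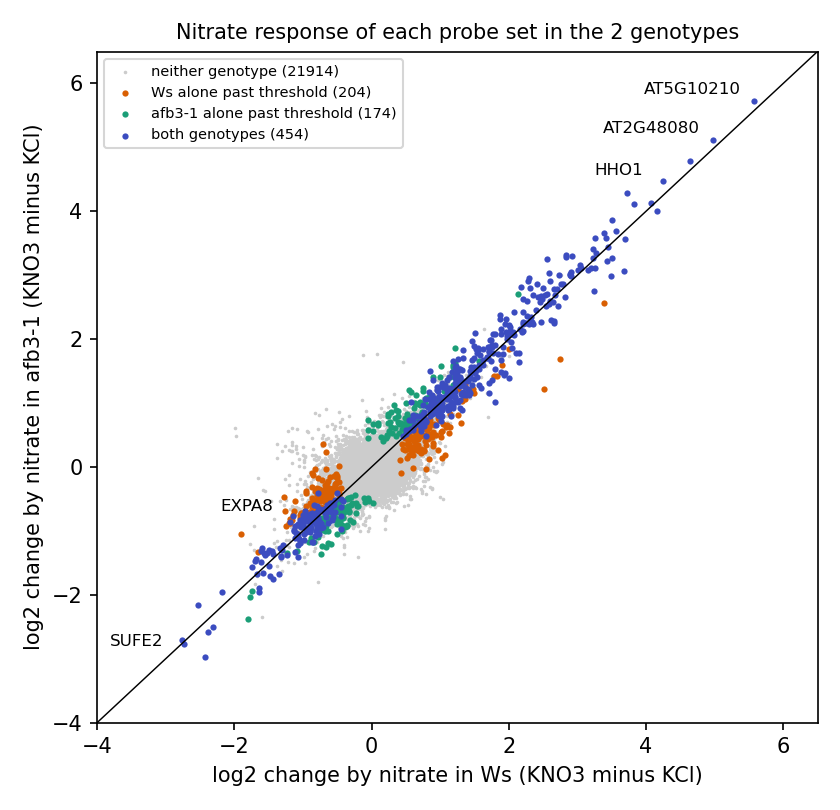
Log2 change by nitrate of each of 22746 probe sets in Ws (horizontal axis) and in afb3-1 (vertical axis), coloured by whether it passed an adjusted p of 0.05 in both genotypes (454), in Ws alone (204), in afb3-1 alone (174) or in neither. The line marks equal changes, and AT5G10210, AT2G48080 and HHO1 lie close to it at the upper end.

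The comparison of afb3-1 with Ws in KCl asked for differences before nitrate is given. No probe set passed (limma, 0 of 22746), with 602 at an unadjusted p under 0.05 (2.65%), and the unmoderated model also gave 0. With same-numbered arrays as pairs, limma also called 0, with 7.10% at an unadjusted p under 0.05 and a smallest adjusted p of 0.639. LBD29 and PUCHI, transcription factors of lateral root initiation, were lower in afb3-1 by point estimate, at −0.42 ± 0.20 and −0.30 ± 0.17 (SE), and LBD16 was at −0.17. The mean signal of LBD29 was 3.14 in Ws KCl and 2.72 in afb3-1 KCl. PUCHI was at 2.16 and 1.86, in the dimmest tertile of probe sets (mean log2 up to 2.32). The list of 3 had a median of −0.30 and an adjusted p of 0.0693, with 0 members past the threshold over all probe sets or adjusted over the list alone. With same-numbered arrays of a treatment as pairs its adjusted p was 0.0107, which was lost again as adjusted p = 0.224 with an estimated correlation (adjusted p = 0.396 with an estimated correlation and no pairs). With the replicate number as a block over all groups it was 0.0456 (adjusted p = 0.274 with an estimated correlation). It was 0.0158 without afb3-1 KCl replicate 3 and 0.0476 without Ws KCl replicate 1 (adjusted p = 0.1502 and adjusted p = 0.330 with an estimated correlation). All 24 spike-in probe sets were lower in afb3-1 than in Ws in KCl by point estimate, with a median of −0.48, and the difference of their means was −0.48, or −0.25 without Ws KCl replicate 3. The auxin-inducible list, which shares LBD29 and LBD16, had an adjusted p of 0.249 (LBD29 and IAA29, the latter at −0.29).

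Nitrate signalling regulators in KCl stood at 0.23 for NRG2 and −0.18 for HHO1 (adjusted p = 0.505), with a median of 0.02 as deposited and −0.02 after quantile normalization. The list reached an adjusted p of 0.0056, higher in afb3-1, without afb3-1 KCl replicate 3, but adjusted p = 0.108 with an estimated correlation. The reductant list, with PGD2 at 0.08 and PGD3 at −0.05, had an adjusted p of 0.731. Its median was −0.01 and its test direction above 0. The 5 named genes with the smallest p, none past the threshold (adjusted p = 0.9999), were AT2G36130 (0.76 ± 0.16 SE), AT1G62350 (−0.62 ± 0.14), AGL48 (−0.40), AT1G32375 (−0.42) and AT1G71740 (−0.56). Other list members stood at 0.12 for RR16, −0.13 for ARR15, 0.07 for GI, −0.04 for BHLH101, 0.30 for STZ, −0.05 for EXPA7, −0.01 for EXPA18, 0.55 for RCA, 0.30 for LHCB4.1 and −0.13 for NRT2.5. In simulated data for this comparison, again with arrays that varied independently, 100% of 4-fold, 76.1% of 2-fold and 29.9% of 1.5-fold changes were recovered.

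The comparison of afb3-1 with Ws after nitrate gave 0 probe sets (limma), with 538 at an unadjusted p under 0.05 (2.37%) and 0 with the unmoderated model. With same-numbered arrays as pairs, limma also called 0, with 7.72% at an unadjusted p under 0.05 and a smallest adjusted p of 0.232. The photosynthesis genes RCA and LHCB4.1, markers of green shoot tissue, had point estimates of 2.15-fold (95% confidence interval of the log2 difference 0.33 to 1.87) and 2.02-fold (−0.01 to 2.04) above Ws, with an adjusted p of 0.9999. RCA, but not LHCB4.1, passed when adjusted over the list alone, of which no other gene was measured. These transcripts also varied between arrays of one group: the mean of 10 nuclear photosynthesis genes was 3.36, 3.27 and 4.31 in the 3 Ws KNO3 arrays and 5.03, 4.51 and 4.82 in the 3 afb3-1 KNO3 arrays. STZ, a zinc finger factor of the wounding list and the only member measured, stood at 0.71 ± 0.23 (SE, unadjusted p = 0.00999, adjusted p = 0.9999). Adjusting over a list of 1 leaves the unadjusted p as it is.

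The 5 named genes with the smallest p after nitrate, none past the threshold, were AT2G35820 (1.24 ± 0.20 SE), AT1G10810 (−0.71), AT2G07719 (0.52), AT1G04420 (0.59) and AT1G66930 (−0.64). None of the tested lists passed: nitrate signalling regulators (HHO3 −0.09 and HHO2 0.06, adjusted p = 0.778), reductant supply (cICDH 0.05 and PGD3 0.03, adjusted p = 0.778), auxin-inducible genes (GH3.1 −0.25 and LBD29 −0.24, adjusted p = 0.472) and lateral root initiation (LBD29 and PUCHI, the latter at −0.15, adjusted p = 0.599). For the nitrate signalling list the test direction was below 0 and the median 0.01. The auxin-inducible list reached an adjusted p of 0.0196, lower in afb3-1, without Ws KNO3 replicate 1, but adjusted p = 0.244 with an estimated correlation. Other members stood at 0.09 for RR16, 0.08 for ARR15, 0.11 for GI, 0.17 for BHLH101, −0.39 for EXPA18, 0.02 for EXPA7 and −0.29 for NRT2.5.

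**Figure D3:**
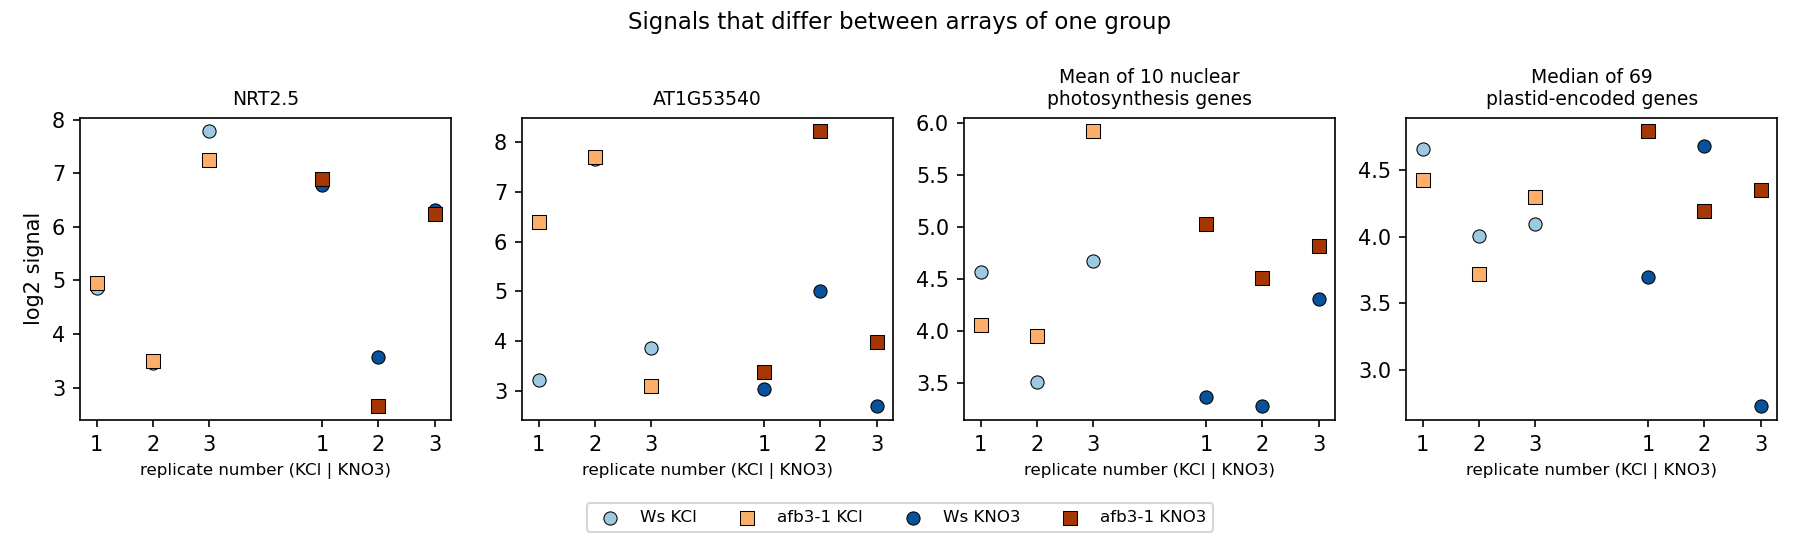
Log2 signal (vertical axis) of NRT2.5, the small heat shock gene AT1G53540, the mean of 10 nuclear photosynthesis genes and the median of 69 plastid-encoded genes on each array, by replicate number within KCl and KNO3 (horizontal axis), with circles for Ws and squares for afb3-1. NRT2.5 was close between same-numbered arrays of the 2 genotypes, such as 7.78 and 7.25 for KCl replicate 3, and the photosynthesis mean was higher in afb3-1 than in Ws in each of the 3 KNO3 pairs.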

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

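Both tests in this part were chosen after the result was seen. The nitrate response of 69 plastid-encoded genes differed between the genotypes by a median of 0.44 on the log2 scale (afb3-1 minus Ws), with an adjusted p of 4.75e-07 in the interaction test of the family at a preset correlation. The median stayed above 0 after quantile normalization (0.45) and median centring (0.49). The result was picked out because the test of the difference passed, although no single member did and adjusted p = 0.932 with an estimated correlation. An effect of the array Ws KNO3 replicate 3, whose median over these genes was 2.72 against 3.70 and 4.68 in the other 2 Ws KNO3 arrays, was not excluded: without it the median difference was 0.27, or 0.63 of its size. A difference between the genotypes with nitrate also stays open, since the median was higher in afb3-1 in 2 of the 3 same-numbered KNO3 pairs. With 3 pairs these 2 explanations cannot be told apart.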

How the results depend on the processing

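Tests with the number within a treatment as a block, and without both KCl arrays numbered 3, were added after the data were seen. The 0 calls between genotypes and for the interaction held under every alternative run. Counts for nitrate in Ws were 338 with only the compared groups (6 arrays), 400 without moderation, 1220 with array weights and 370 to 680 leaving out single arrays, against 658. For afb3-1 they were 416 without moderation, 1612 with array weights and 380 to 772 leaving out single arrays, against 628. Apart from fewer arrays, the cause was not tested. The correlation of the responses ran from 0.615 to 0.790 and the overlap from 316 to 469 leaving out single arrays. With the replicate number as a fixed block, 973 and 936 probe sets were called in Ws and afb3-1, and 911 and 799 with a random block. The number pairs KCl with KNO3 arrays only in part. Not every array correlated best with its own number across treatments. A random block within treatment gave 744 and 675, and leaving out both KCl arrays numbered 3 gave 667 and 728. Among the tests between genotypes and of the interaction, fixed pairs within a treatment changed the call of the lateral root initiation list in KCl and no other. The replicate number as a fixed block over all groups also changed that test (adjusted p = 0.0456). In the block and leave-one-out settings where a list call changed, the adjusted p with an estimated correlation, added after the data were seen, ran from 0.108 to 0.330.

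Of 40 named calls, 985 of 1000 values under alternatives stayed past the threshold and none changed sign; 15 values of 5 genes did not pass. For 79 list values given without a call, stability was judged by size and not by sign, a choice made after sign changes had been seen. Of 1986 such values under alternatives 104 changed sign, in 39 of the 79, 11 moved by more than the spread between replicates, and WES1 in Ws passed without Ws KNO3 replicate 2 (adjusted p = 0.0315). Among list tests that did not pass, the interaction of the reductant list changed direction with the replicate block (adjusted p = 0.975), with fry (0.821) and with the block within treatment (0.978). Leaving out single arrays, the adjusted p of list tests that changed direction at least once ran from 0.269 to 0.963 for lateral root initiation with nitrate in afb3-1. For the interaction it ran from 0.524 to 0.953 for the reductant list and from 0.386 to 0.953 for auxin-inducible genes. In KCl between genotypes it ran from 0.0056 to 0.984 for nitrate signalling and from 0.607 to 0.983 for the reductant list. In KNO3 it ran from 0.551 to 0.950 for nitrate signalling, from 0.456 to 0.873 for the reductant list and from 0.0196 to 0.889 for auxin-inducible genes. The cause was not tested. The alternative of a pseudocount does not apply to log2 values. Signal near the floor limits the fold of dim genes.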

Other observations

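The tests on photosynthesis genes, the families named here and the blocks within a treatment were chosen after the data were seen. The splits of the samples were not, and the tests on small p-values were set before their results were seen, when it was already known that the block gave 0 calls. Averaged over both genotypes, with each same-numbered pair of a treatment averaged first (3 pairs against 3), nitrate changed 534 probe sets, 359 higher and 175 lower. The count was 1045 (607 higher and 438 lower) with a random block for the number within a treatment. It was 1515 (790 higher and 725 lower) when the 12 arrays were taken as independent, which the shared deviations of same-numbered arrays contradict. The following genes were chosen after their values were seen. XTH20, a xyloglucan-modifying enzyme, rose by 1.13 in Ws and 0.91 in afb3-1 on the log2 scale (adjusted p = 0.00161 and 0.00628). EXLB1 of the expansin family changed by −0.88 and −0.96 (adjusted p = 0.00612 and 0.00348), and TBL38 of the TBL cell wall acetylation family by −0.998 and −0.92 (adjusted p = 0.00304 and 0.00521). The transcription factor bZIP58 rose by 1.44 and 1.16 (adjusted p = 0.00458 and 0.0176), and UGT80B1, a sterol glucosyltransferase, changed by −0.87 and −0.73 (adjusted p = 0.00289 and 0.00876). As families, UDP-glycosyltransferases (51 genes, median −0.20, adjusted p = 0.0106) and plastid-encoded genes (69 genes, median −0.30, adjusted p = 0.0106) were lower with nitrate in Ws at a preset correlation, and both had adjusted p = 0.898 with an estimated correlation. With nitrate, plastid-encoded genes had a median difference of 0.34 between afb3-1 and Ws (adjusted p = 1.71e-15, but adjusted p = 0.67 with an estimated correlation), which was 0.205 without Ws KNO3 replicate 3. Their median per array was lower in afb3-1 by 0.49 in KNO3 pair 2. An exact permutation test of the array medians, which did not use the pairs, gave a two-sided p = 0.3.

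Some transcripts differed more between arrays of one group than between groups. NRT2.5 spanned 2.65 to 6.89 in afb3-1 KNO3 and 3.49 to 7.25 in afb3-1 KCl, and was close between same-numbered arrays of the 2 genotypes within a treatment. The small heat shock genes AT1G53540, AT1G52560 and AT2G29500, chosen after their values were seen, were at 7.69, 5.75 and 7.34 in afb3-1 KCl replicate 2 and at 3.097, 1.35 and 3.83 in afb3-1 KCl replicate 3. AT1G53540 also differed between same-numbered arrays, at 6.40 in afb3-1 and 3.22 in Ws for KCl replicate 1 and at 8.21 and 5.003 for KNO3 replicate 2.

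The 24 probe sets of dap, lys, phe and thr, bacterial transcripts used as spike-in controls, were left out of the gene tests and summarized as a set after their values were seen. The set mean per array ran from 3.18 to 4.33, below the mean of the hybridization control bioB (4.79). Whether the signal came from added transcripts or from background was not tested. Between genotypes in KCl all 24 were lower in afb3-1, with a median of −0.48 and 15 at an unadjusted p under 0.05. The 5′ probe set of thr passed (−0.84, adjusted p over 64 controls = 0.0192). With nitrate in Ws all 24 were lower, with a median of −0.40 and 8 at an unadjusted p under 0.05, and for the interaction all 24 were above 0, with a median of 0.43. The control TrpnX was not in the set and did not share this pattern. Its probe sets stood at 0.08, −0.10 and −0.01 between genotypes in KCl and at 0.12, −0.02 and −0.03 with nitrate in Ws. For the interaction they stood at −0.05, 0.11 and 0.17. Without Ws KCl replicate 3 the interaction of the set mean was 0.19 against 0.42 with all arrays, and the nitrate change of the set mean in Ws was −0.15 against −0.38. In KNO3 between genotypes 18 of 24 were lower, with a median of −0.05, and with nitrate in afb3-1 it was 6 of 24, with a median of 0.05. The mean of the set was 3.54, 3.71 and 4.33 in the Ws KCl arrays and 3.18, 3.51 and 3.45 in the afb3-1 KCl arrays, in order of replicate number (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). This test did not use the pairs, and afb3-1 was lower in each same-numbered KCl pair. The difference of the set means in KCl, −0.48, was −0.25 without Ws KCl replicate 3. The set is not among the results for a closer look because only rises were listed there for controls, a rule written after the thr value was seen.

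Comparisons between genotypes gave fewer small p-values than the 5% chance gives (2.65% in KCl, 2.37% in KNO3 and 2.92% for the interaction). Probe sets near the floor of the scale are argued against as the cause, since the share was at most 1.87% in the brightest tertile. Deviations shared by same-numbered arrays within a treatment are a candidate explanation: with the number within a treatment as a block the shares were 7.10%, 7.72% and 9.11%. Whether an effect of the genotype spread over many genes adds to this cannot be told apart from chance: 8 of the 32 flips of the genotype within pairs gave at least the 1347 probe sets of the real labels for the average over treatments (highest other 2510). For the interaction, 2 of the 32 flips gave at least 2073: the real labels and another, which gave 2510. Both counts out of 32 include the real labels.

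With nitrate, the mean of 10 photosynthesis genes of the nucleus stood higher in afb3-1 than in Ws by 1.14 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give), and all 10 had a positive difference, with a median of 1.15 as deposited, 1.15 after quantile normalization and 1.16 after median centring. The permutation test did not use the pairs. Green tissue or greening that differed between root samples may account for the higher photosynthesis signal. Within groups the 10 genes moved together, with a median pairwise correlation of 0.915. Genes regulated together would also do so, so this cannot tell the causes apart. In KNO3 pairs 1, 2 and 3 the photosynthesis mean differed by 1.67, 1.24 and 0.51 (afb3-1 minus Ws). The median of plastid-encoded genes differed by 1.09, −0.49 and 1.62. The mean log2 signals of RCA, LHCB4.1, PSBW and PSAE-1 were 6.20, 5.58, 4.93 and 4.92, which depend on each probe set and give no order of abundance. A steady effect of afb3-1 in both treatments stays open, with the list mean higher in afb3-1 in 5 of 6 same-numbered pairs and lower by 0.51 in KCl replicate 1. Regulation of these genes inside the root by genotype was not separated from shoot tissue, and the name pattern behind the list was written after 5 of its genes had been seen.

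Other splits of the samples were counted for each comparison. For nitrate, the real split of 6 arrays called 658 probe sets in Ws and 628 in afb3-1, and the highest of the other 9 splits called 0 in each, so 1 of 10 splits reached the real count. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. At an unadjusted p under 0.05, 1 other split of the Ws arrays gave 3516 probe sets against the real 3016. It set KCl replicates 1 and 2 and KNO3 replicate 2 against KCl replicate 3 and KNO3 replicates 1 and 3. The same split of the afb3-1 arrays gave 2384 against the real 2528. It keeps together Ws arrays that deviated together across treatments (correlations of 0.542 and 0.543). Whether these shared deviations account for the count was not tested. For afb3-1 against Ws, all 10 splits in KCl and all 10 in KNO3 called 0, which is also the real count. Splits that part all 3 same-numbered pairs gave 224 to 990 probe sets at an unadjusted p under 0.05 in KCl against the real 602, and 148 to 330 in KNO3 against 538. Splits that part 1 pair gave 683 to 3667 and 723 to 1569. For the interaction the real count was also 0, which each of the 100 drawn splits reaches whatever the data, and the highest called 3, so this count decides nothing about chance.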
